A study of Mus musculus with 9 samples.

How the data were processed

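The data were poly-A RNA-seq libraries from mouse ES cells, 3 from unedited cells (WT) and 3 from each of 2 Kif2a knockout lines (KO1 and KO2). Per the labels, the cells were of a 129 background, RNA was taken up in Trizol, and stranded TruSeq libraries were read on a NextSeq2000 as paired ends of 50 bases. Per the submitters' processing notes, HISAT2 and DESeq2 were used with the GRCm38 build; their versions, the annotation, the filter on genes and whether reads were counted by strand are not given in the sources used here. The alignment, counting and scaling are those of the authors, and raw reads were not analysed here.

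The deposited values are a signal per gene and library that the authors had already scaled: 15526 genes in 9 columns, with column totals of 1739907 to 1806666. The plan had assumed counts, but normalized values were found. In each library 100% of the values were whole multiples of 1 smallest step, within a tolerance of 0.05 reads, and dividing by that step recovered whole reads. The recovered depth was 17179732, 14960295 and 15177354 reads in the WT libraries, 18019079, 16962661 and 18814858 in KO1, and 15076503, 15057363 and 17575608 in KO2. The smallest total over the 9 libraries was 14 reads, and 0 genes were at 0 in all libraries. The authors' scaling factor of WT replicate 2 was 1.03 times its median-ratio factor. For genes with low counts the variance between libraries of a group was 1.98 (WT), 2.35 (KO1) and 2.02 (KO2) times the mean, so counting error alone understates the spread. No 2 libraries of a group were duplicates of each other.

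Gene positions came from GENCODE M21 by symbol, for 98.1% of the genes, and 298 had none. The annotation the authors used may differ from it. The table has 15504 distinct symbols.

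Genes with a mean value of at least 10 over the 9 libraries were tested, 10238 in all. limma 3.58.1 in R 4.3.3 was fitted to log2 of the value with a pseudocount of 1, with a mean per group, a trend of the variance with the level and robust moderation. The comparisons were KO1 against WT, KO2 against WT, the mean of both KO lines against WT, and KO2 against KO1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Kif2a was also tested with an exact two-sided permutation test over all 84 assignments of the 9 libraries. The overlap between the lines was set against 100 simulated data sets without effects in which both lines shared the WT libraries, since 3 control libraries cannot be split between the lines.

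The choices of test, filter, gene lists, naming rule and most settings tried besides were made before the data were examined; limma took the place that the plan gave to it for normalized values. Kif2a is named in the text. From the mean contrast come the 10 highest and 10 lowest genes called there and in both single-line contrasts with the same sign. They needed a mean value of at least 100 and all knockout libraries on one side of the WT libraries. From KO2 against KO1 come the 6 highest and 6 lowest genes called there, with the same mean value. Their KO2 libraries had to lie on one side of the KO1 libraries, and no call against WT was needed. Also named are up to 4 members with the smallest adjusted p of each list described, and 8 fixed markers (Pou5f1, Nanog, Sox2, Cdkn1a, Mdm2, Kif2b, Kif2c and Kif24). Predicted genes, clone names and pseudogenes were passed over. Other genes are said to have been named after their values were seen.

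The 30 gene lists were kinesin-13 family, mitotic kinesins, cytokinesis and midbody, ESCRT and abscission, tubulins, microtubule regulators, G2/M and spindle assembly, DNA replication and S phase, naive and general pluripotency, formative and primed pluripotency, two-cell-like state, primitive endoderm, primitive streak and mesendoderm, mesoderm, neuroectoderm and neurons, trophoblast, fibroblast (feeder) markers, p53 targets, YAP/TEAD targets, integrated stress and unfolded protein response, hypoxia and glycolysis, imprinted genes, methylation-sensitive germline genes, FGF/ERK immediate and feedback targets, WNT/beta-catenin targets, primary cilium and centriole, cholesterol synthesis, ribosomal proteins, mitochondrially encoded genes, and extracellular matrix and adhesion. They were written from general knowledge of the genes. The 25 with at least 5 tested genes were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a set's genes move on balance one way and compares it with no other genes. Chromosomes were tested with camera in the same way. Adjusted p-values of lists are over the 25 lists of a comparison.

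The calls were tested on simulated data, negative binomial counts at the mean levels and dispersions of these libraries, with changes of 1.25, 1.5, 2 and 4-fold in both knockout lines for 200 genes and in KO2 alone for another 200. They recovered 66% of the 1.25-fold changes in KO1 against WT, 78% in KO2 against WT, 90% in the mean contrast and 60% in KO2 against KO1. At 1.5-fold the shares were 97.9%, 100%, 100% and 96%, and at 2-fold and 4-fold they were 100% in all 4 comparisons. Of the calls, 5.49%, 5.07%, 5.90% and 2.76% were false in these comparisons.

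The alternatives tried were quantile normalization, no filter, a mean value of at least 100, DESeq2 1.42.0 on the recovered reads, limma without a trend, pseudocounts of 0.1 and 10, a replicate block, the libraries of a comparison alone, an absolute log2 fold change of at least 1, the KO libraries pooled as 1 group, and leaving out each library in turn. Chosen after seeing the data were edgeR 4.0.16 quasi-likelihood tests on the recovered reads, with TMM and with RLE factors, and median-ratio scaling of the recovered reads before limma. With edgeR and TMM, 102 genes were called in KO1, 1915 in KO2, 892 in the mean contrast, 62 in both lines the same way and 1060 between the lines. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.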

Results

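Poly-A RNA from mouse ES cells of a 129 background was compared between unedited cells (WT) and 2 separately edited lines without Kif2a (KO1 and KO2), with 3 libraries per group. Kif2a encodes a kinesin-13 motor, which depolymerises microtubule ends. Gene levels are given as normalised read counts, mean ± SD over 3 libraries, and changes as log2 fold changes ± SE. Adjusted p-values come from limma over 10238 genes unless another tool is named. The recovered depth was 14960295 to 18814858 reads per library. The p-values measure only the spread between these samples, since nothing in the labels says that the 3 libraries of a group were separate cultures and each knockout line is 1 clone. The first principal component held 36.3% of the variance and set the KO2 libraries (9.5 to 10.7) apart from WT (−5.6 to −11.0), with KO1 between them (−1.1 to −2.5).

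Kif2a (ENSMUSG00000021693, chromosome 13, 106958996 to 107022126 in GRCm38, minus strand) fell by 5.85 ± 0.18 on the log2 scale in KO1 and by 5.75 ± 0.18 in KO2 (limma adjusted p = 1.7e-32 and 4.0e-32). These values include the pseudocount of 1, which makes them smaller at so low a level, and the means of WT and of the 6 knockout libraries differ 105-fold. The Kif2a level was 114 ± 6.49 in WT, 0.999 ± 0.140 in KO1 and 1.17 ± 0.528 in KO2. Over the 6 knockout libraries this left 0.952% of the WT level. The WT libraries held 1049, 1043 and 959 Kif2a reads, the KO1 libraries 9, 11 and 10, and the KO2 libraries 9, 6 and 17. The 6 knockout libraries lay below the 3 WT libraries (exact two-sided permutation test, p = 0.0238, the smallest that the 84 assignments allow). The kinesin-13 paralog Kif2c, which acts at kinetochores, stood at 304 ± 9.89 in WT, 303 ± 4.56 in KO1 and 288 ± 10.9 in KO2 and had no call (mean of both lines −0.04 ± 0.04, adjusted p = 0.56). Kif24, a centriolar kinesin-13, also had no call (0.15 ± 0.08, adjusted p = 0.23), and Kif2b is not in the table.

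**Figure D1:**
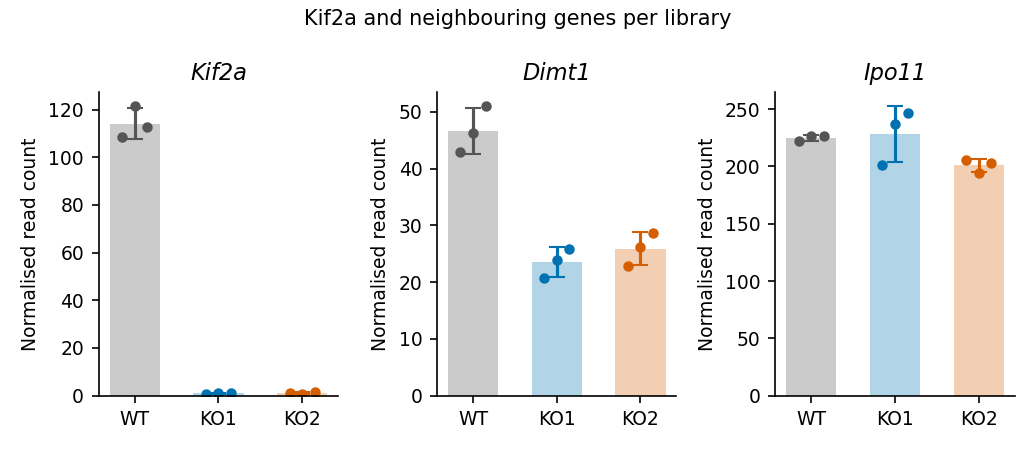
Normalised read counts (y axis) of Kif2a and its neighbours Dimt1 and Ipo11 in WT, KO1 and KO2; bars are means of 3 libraries, error bars the SD and points single libraries. Kif2a falls from 114 in WT to 0.999 and 1.17 in the knockout lines, and Dimt1 from 46.7 to 23.5 and 25.9.

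In KO1 against WT, the comparison that asks what changed in the first edited line, the Y-linked genes Ddx3y, an RNA helicase, and Eif2s3y, a subunit of the initiation factor eIF2, rose by 0.84 ± 0.06 and 1.01 ± 0.06 (limma adjusted p = 3.1e-16 and 3.0e-20). Bhmt, which methylates homocysteine with betaine, rose from 85.5 ± 3.67 to 135 ± 3.22 (0.65 ± 0.06, adjusted p = 1.9e-11). Lamb1, a laminin chain, rose by 0.42 ± 0.07 (adjusted p = 3.1e-05), and Dppa3, a naive pluripotency marker, by 0.38 ± 0.06 (4.0e-05). Dsp, the desmosomal protein desmoplakin, rose by 0.36 ± 0.06 (1.1e-04), and Gpx1, a glutathione peroxidase, fell by 0.29 ± 0.05 (4.0e-05). The glucose transporter Slc2a3 rose by 0.19 ± 0.04 (6.0e-04). Apart from Kif2a, the largest fall among the called genes was that of its neighbour Dimt1 (−0.96 ± 0.10).

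In total 109 genes were called in KO1, 85 higher and 24 lower, and 1304 genes had an unadjusted p under 0.05. Of these calls 11 higher and 2 lower reached 1.5-fold. The share of higher calls depended on scaling. The main values gave 85 higher and 24 lower, quantile normalization 65 and 38, median-ratio scaling 62 and 42, edgeR 60 and 42, and DESeq2 66 and 43. Leaving out 1 library moved the number of calls to 65 (without WT replicate 3), 54 (without KO1 replicate 1), 50 (without KO1 replicate 2) or 166 (without KO2 replicate 3).

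By camera 3 lists were called in KO1 and by fry none. The neuroectoderm and neurons list was lower as a set by camera (camera adjusted p = 0.0031 over 25 lists; adjusted p = 0.45 with an estimated correlation; fry adjusted p = 0.076). Of its 7 tested genes 2 fell over all genes, the neurofilament gene Nefm and the tubulin-binding Stmn2, and 3 fell adjusted over the list alone. Nefm fell by 0.43 ± 0.09 (adjusted p = 0.0077), a call that was lost without WT replicate 1 (−0.41) and without KO1 replicate 1 (−0.36). Stmn2 fell by 0.22 ± 0.05 (adjusted p = 0.013), and its call was lost without WT replicate 2 (−0.21), WT replicate 3 (−0.21), KO1 replicate 1 (−0.20) or KO1 replicate 3 (−0.22). Set calls of camera at the edge of the threshold, both at 0.28 by fry, were formative and primed pluripotency, lower (0.048; adjusted p = 0.70 with an estimated correlation), and hypoxia and glycolysis, higher (0.048; adjusted p = 0.72 with an estimated correlation). Of 14 formative genes only the transcription factor gene Foxd3 fell over all genes (−0.45 ± 0.12, adjusted p = 0.033), and 4 fell adjusted over the list alone. The Foxd3 call was lost without WT replicate 1 (−0.42), WT replicate 2 (−0.43), KO1 replicate 1 (−0.33) or KO1 replicate 2 (−0.48). Of 29 hypoxia and glycolysis genes only Slc2a3 rose over all genes, and 9 rose adjusted over the list alone. The formative call was lost without WT replicate 1 (0.057), WT replicate 3 (0.18), KO1 replicate 1 (0.15), KO1 replicate 2 (0.075) or KO2 replicate 1 (0.051), under quantile normalization (0.074) and under median-ratio scaling (0.078). The hypoxia and glycolysis call was lost without WT replicate 1 (0.11), WT replicate 3 (0.10), KO1 replicate 1 (0.21), KO1 replicate 2 (0.10) or KO2 replicate 1 (0.051), and under median-ratio scaling (0.078).

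In KO2 against WT, which asks the same of the second line, Dsp rose from 100 ± 3.37 to 160 ± 9.20 (0.66 ± 0.06, limma adjusted p = 1.7e-12), and the last enzyme of cholesterol synthesis, Dhcr7, rose from 103 ± 8.22 to 162 ± 11.5 (0.64 ± 0.06, adjusted p = 2.4e-11). Ncor1, a nuclear receptor co-repressor, fell from 780 ± 31.2 to 488 ± 13.8 (−0.68 ± 0.04, adjusted p = 1.4e-19). Gpx1 fell from 451 ± 14.9 to 287 ± 13.3 (−0.65 ± 0.05, 2.6e-16), and Vim, the intermediate filament vimentin, fell by 0.49 ± 0.04 (1.3e-12). The neuronal beta-tubulin Tubb3 fell from 88.7 in WT to 55.8 in KO2, and the hypoxia-induced mitophagy gene Bnip3 rose from 74.3 to 117.

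Lists fixed before the data were examined showed 9 calls in KO2 by camera, and none of the 9 held with an estimated correlation. By fry ribosomal proteins (adjusted p = 0.060) and mitochondrially encoded genes (0.068) were not called. Cholesterol synthesis was higher, with 17 of 22 genes up over all genes and 19 adjusted over the list alone, a median of 0.28 and camera adjusted p = 9.0e-12 (adjusted p = 0.13 with an estimated correlation). Its regulator Insig1 rose by 0.46 ± 0.06, the sterol oxidase Msmo1 by 0.44 ± 0.06 and the demethylase Cyp51 by 0.48 ± 0.06. Hypoxia and glycolysis was higher with 23 of 29 genes up and 1 down, over all genes and adjusted over the list alone alike (camera adjusted p = 8.2e-10; adjusted p = 0.30 with an estimated correlation). Slc2a3, Bnip3 and the glucose transporter Slc2a1 rose by 0.41 ± 0.04, 0.64 ± 0.07 and 0.34 ± 0.04. Of 54 ribosomal protein genes 19 rose over all genes and 26 adjusted over the list alone, with a median of 0.09 (camera 1.6e-04; adjusted p = 0.53 with an estimated correlation). The number that rose over all genes was 12 under quantile normalization and 14 under median-ratio scaling.

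DNA replication and S phase genes were lower in KO2, with 8 of 35 down over all genes and, adjusted over the list alone, 11 down and 1 up (camera adjusted p = 0.0013; adjusted p = 0.37 with an estimated correlation). Over all genes 11 were down under quantile normalization and 12 under median-ratio scaling. The S-phase cyclin gene Ccne1 fell from 302 in WT to 260 in KO2, and the nucleotide synthesis gene Tyms from 211 to 185. Of 8 mitochondrially encoded genes 3 fell, over all genes and adjusted over the list alone (camera 0.0034; adjusted p = 0.37 with an estimated correlation). They were mt-Cytb and mt-Nd1, of respiratory complexes III and I, and mt-Nd6, also of complex I. The mt-Nd1 change of −0.33 ± 0.06 lost its call without WT replicate 2 (−0.29), and the mt-Nd6 change of −0.40 ± 0.11 without WT replicate 3 (−0.32) or KO2 replicate 1 (−0.27). One KO2 library stood apart in the share of reads of all mitochondrially encoded genes in the table, tested or not. They held 0.847% and 0.860% of the reads in KO2 replicates 1 and 2 but 1.03% in replicate 3, against 0.962% to 1.08% in WT. Without KO2 replicate 3, 6 of the 8 fell. Neuroectoderm and neurons had 1 gene up and 4 down over all genes, and 1 up and 5 down adjusted over the list alone (camera 0.0058; adjusted p = 0.30 with an estimated correlation). Tubb3 fell by 0.66 ± 0.07, Nefm by 0.60 ± 0.09 and the neurofilament gene Nefl by 0.44 ± 0.08, while the progenitor filament gene Nes rose by 0.19 ± 0.05. WNT/beta-catenin targets had 4 of 9 genes down over all genes, and 4 down and 1 up adjusted over the list alone (camera 0.020; adjusted p = 0.37 with an estimated correlation), a call lost without KO2 replicate 3 (0.10). Those that fell were the cyclin gene Ccnd1 (−0.46 ± 0.05), the feedback inhibitors Axin2 (−0.46 ± 0.06) and Notum (124 in WT and 83.1 in KO2), and Sp5 (−0.78 ± 0.14).

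Primitive endoderm genes were higher in KO2, with 5 of 10 up over all genes and adjusted over the list alone (camera adjusted p = 0.0058; adjusted p = 0.37 with an estimated correlation), among them the lipoprotein gene Apoe (0.27 ± 0.04), the laminin gene Lama1 (0.23 ± 0.05) and the endoderm regulator Gata4, which went from 12.6 ± 1.49 to 20.2 ± 0.306. Extracellular matrix and adhesion genes were higher, with 13 up and 3 down of 28 over all genes, and 13 up and 4 down adjusted over the list alone (camera 0.022; adjusted p = 0.37 with an estimated correlation), a call lost without KO2 replicate 1 (0.072). Lama1, Lamb1, Lamc1, Col4a1, Col4a2 and Sparc are on both the primitive endoderm and the extracellular matrix lists, so the calls of these lists are not independent. The integrin Itga6 rose by 0.29 ± 0.05 and the cadherin Cdh3 by 0.32 ± 0.06. Beside these, all 3 tested genes of the fibroblast (feeder) markers list rose in KO2: Fbln2 (14.9 ± 1.84 to 23.1 ± 0.668), Pdgfrb (14.5 ± 0.580 to 22.8 ± 1.77) and Col5a1 (77.5 ± 4.11 to 97.9 ± 2.96), named after their values were seen. None of the 3 was called in KO1.

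In total 1892 genes were called in KO2, 1123 higher and 769 lower, with 42 higher and 22 lower by at least 1.5-fold. The direction split moved with scaling, from 1123 higher and 769 lower to 897 and 1023 under median-ratio scaling, 917 and 994 under edgeR with RLE factors, and 794 and 899 under DESeq2.

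The mean of both KO lines against WT asks what changed on average over the lines, and it also calls changes of 1 line alone, such as that of Ncor1 (−0.33 ± 0.03, limma adjusted p = 3.5e-10). In this contrast Bhmt, Dsp and Dhcr7 rose the most by the fixed naming rule, by 0.53 ± 0.05, 0.51 ± 0.05 and 0.47 ± 0.05 (limma adjusted p = 1.6e-10, 1.7e-10 and 8.5e-09). Itpr1, an endoplasmic reticulum calcium channel, rose by 0.38 ± 0.05, the folate enzyme gene Aldh1l1 by 0.37 ± 0.05, Lamb1 by 0.36 ± 0.06, Dppa3 by 0.34 ± 0.05, the acyl-CoA synthetase gene Acsl1 by 0.31 ± 0.05, Slc2a3 by 0.30 ± 0.03 and Mroh1 by 0.29 ± 0.05. Gpx1 fell by 0.47 ± 0.04 and Vim by 0.34 ± 0.04 (adjusted p = 7.0e-13 and 3.9e-09). Mllt6 went from 550 ± 28.5 in WT to 489 ± 20.4 in KO1 and 439 ± 23.4 in KO2. The splicing-related gene Zmat2 fell by 0.21 ± 0.04, Trp53, which encodes p53, by 0.21 ± 0.03 and Stmn2 by 0.19 ± 0.04. The recombination gene Sfr1 was 265 ± 6.21 in WT, 234 ± 11.3 in KO1 and 242 ± 3.78 in KO2 (limma adjusted p = 0.011), a call lost without WT replicate 2 (−0.15) or WT replicate 3 (−0.14). With the KO libraries pooled as 1 group, so that the difference between the lines counts as spread, Dhcr7 (adjusted p = 0.058), Gpx1 (0.096), Vim (0.082) and Sfr1 (0.067) lost their calls in this contrast. The rule also needed a call in KO1, and leaving out each of the 9 libraries in turn lost that call 3 times for Dhcr7, 4 times for Vim, Trp53 and Stmn2, 5 times for Mllt6, Acsl1, Mroh1 and Zmat2, and 7 times for Sfr1; the KO2 call was lost 3 times for Stmn2 and 8 times for Sfr1. In each of the genes named by the rule the 6 knockout libraries lay on one side of the 3 WT libraries, which the naming rule required, and 32 higher and 7 lower genes met the rule.

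The mean contrast called 931 genes, 631 higher and 300 lower. Under quantile normalization the split was 482 higher and 421 lower, under median-ratio scaling 459 and 479, under edgeR 444 and 448, under edgeR with RLE factors 430 and 463, and under DESeq2 367 and 424. Without WT replicate 2 the count was 511 and without WT replicate 3 it was 581.

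Of the 25 lists tested, 7 were called by camera in the mean contrast and none of the 7 held with an estimated correlation. Of the 7 only neuroectoderm and neurons and hypoxia and glycolysis were also called in KO1, and by fry DNA replication and S phase (adjusted p = 0.14) and mitochondrially encoded genes (0.19) were not called. Cholesterol synthesis rose with 13 of 22 genes up over all genes and 16 adjusted over the list alone (median 0.17, camera adjusted p = 4.9e-09; adjusted p = 0.23 with an estimated correlation), while in KO1 1 of 22 rose and the list had no call (0.095). With the KO libraries pooled as 1 group, its members Insig1, Msmo1 and Cyp51 lost their calls in this contrast (limma adjusted p = 0.20, 0.22 and 0.16), as did Bnip3 (0.21), Slc2a1 (0.069), Gata4 (0.19), mt-Cytb (0.29), mt-Nd1 (0.21) and mt-Nd6 (0.14) of other lists. Hypoxia and glycolysis rose with 15 of 29 genes up over all genes and 20 adjusted over the list alone (median 0.13, camera 1.0e-07; adjusted p = 0.38 with an estimated correlation). Neuroectoderm and neurons was lower, with 1 up and 4 down of 7 over all genes and 1 up and 5 down adjusted over the list alone (median −0.19, camera 0.0011; adjusted p = 0.23 with an estimated correlation). Mitochondrially encoded genes were lower, with 3 of 8 down both over all genes and adjusted over the list alone (camera 0.0044; adjusted p = 0.41 with an estimated correlation), a call lost without WT replicate 2 (0.14); 2 were down under median-ratio scaling, and 5 without KO2 replicate 3, the library with the higher mitochondrial share. DNA replication and S phase was lower as a set (median −0.04, camera 0.0061; adjusted p = 0.41 with an estimated correlation), with 1 of 35 genes down over all genes and 0 adjusted over the list alone. Over all genes 4 were down under quantile normalization and 5 under median-ratio scaling. The gene down in the main fit, the ribonucleotide reductase gene Rrm2, fell by 0.12 ± 0.04 (adjusted p = 0.024) and lost its call without WT replicate 1 (−0.10), WT replicate 3 (−0.13), KO1 replicate 2 (−0.11), KO2 replicate 1 (−0.11) or KO2 replicate 2 (−0.11). Extracellular matrix and adhesion had 11 up and 2 down of 28 over all genes and 12 up and 2 down adjusted over the list alone (camera 0.022; adjusted p = 0.41 with an estimated correlation), a call lost without KO2 replicate 1 (0.051). Primitive endoderm had 4 of 10 up both over all genes and adjusted over the list alone (camera 0.038; adjusted p = 0.41 with an estimated correlation), a call lost without WT replicate 2 (0.071), KO1 replicate 2 (0.061), KO1 replicate 3 (0.054) or KO2 replicate 1 (0.081). The primitive endoderm and extracellular matrix lists share laminin and collagen IV genes, so their calls are not independent here either. Fbln2 and Pdgfrb of the fibroblast list, singled out after their values were seen, also rose in this contrast. The direction of all 7 lists was the same under quantile normalization and median-ratio scaling. Over all genes these gave 11 and 9 genes up for cholesterol synthesis, and 7 and 8 up with 2 down in each for extracellular matrix and adhesion.

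**Figure D2:**
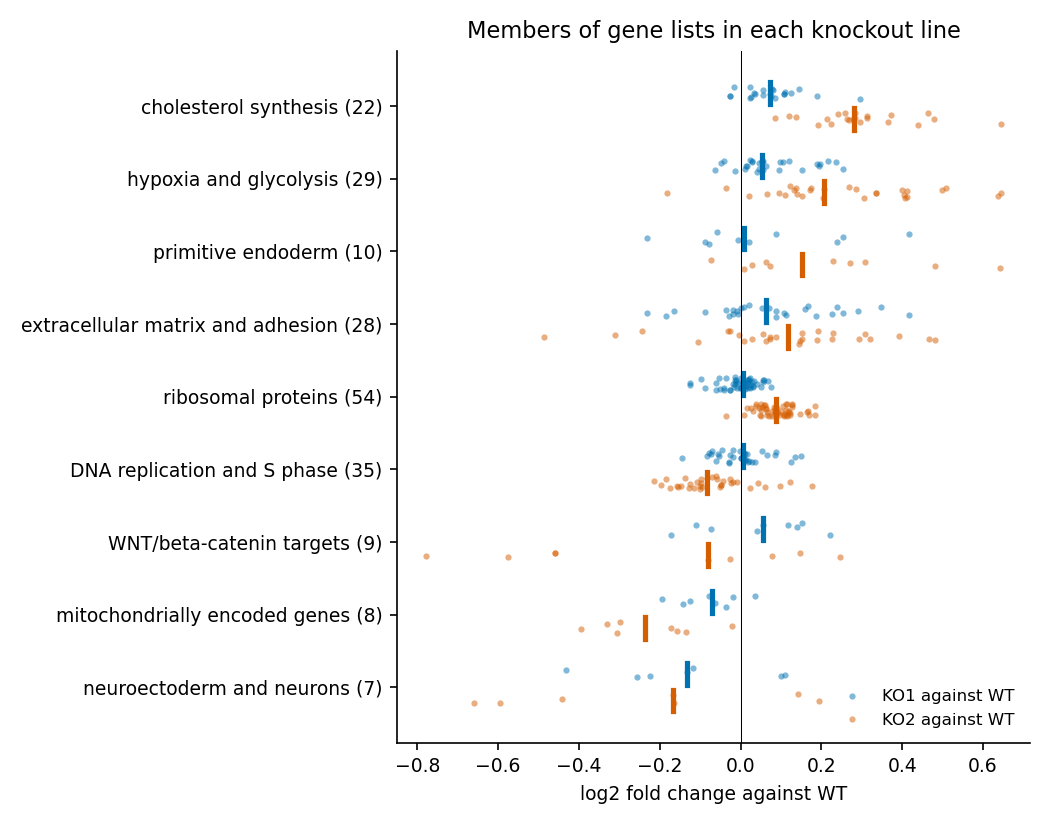
Log2 fold change against WT (x axis) of the tested members of 9 gene lists (y axis) in KO1 and in KO2; each point is 1 gene and each bar the median of a list in that line. Cholesterol synthesis has a median of 0.07 in KO1 and 0.28 in KO2, and neuroectoderm and neurons −0.13 and −0.17.

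The cell-division groups closest to KIF2A's role had no list call in the mean contrast. Of 13 mitotic kinesins none rose or fell, over all genes or adjusted over the list alone (camera adjusted p = 0.18), but Kifc1 (−0.11 ± 0.04, limma adjusted p = 0.097) was called lower by DESeq2 (0.033), edgeR (0.042) and under median-ratio scaling (0.035), and Kif14 higher without KO1 replicate 3 (0.039). Of 28 cytokinesis and midbody genes 1 rose on both counts (0.88), and of 29 ESCRT and abscission genes 3 rose on both counts (0.66). The ESCRT genes Pdcd6ip (0.18 ± 0.05) and Chmp2a (0.20 ± 0.05) were called by limma at adjusted p = 0.0052 and 0.0072; the Pdcd6ip call was lost without WT replicate 1 (0.16) and the Chmp2a call without WT replicate 2 (0.17). Ist1, the other one that rose (0.14 ± 0.04, limma adjusted p = 0.040), and the cytokinesis gene Arhgef2 (0.20 ± 0.06, 0.019) lost their calls under edgeR and DESeq2. The cytokinesis gene Birc5 (−0.12 ± 0.04, 0.064) was instead called lower by DESeq2 (0.010), edgeR (0.024), under quantile normalization (0.037) and under median-ratio scaling (0.018), so the direction of that list's calls depended on the setting. Ist1 also lost it without WT replicate 1 (0.13), WT replicate 2 (0.10), KO1 replicate 1 (0.13), KO1 replicate 2 (0.13) or KO2 replicate 3 (0.12), and Arhgef2 without WT replicate 1 (0.20), WT replicate 3 (0.18) or KO1 replicate 2 (0.18). Of 13 tubulin genes 1 rose (Tubb6) and 1 fell (Tubb3) over all genes, and 2 rose and 1 fell adjusted over the list alone (camera 0.99). The Tubb6 rise of 0.17 ± 0.05 lost its call under median-ratio scaling, without WT replicate 2 (0.11) and without KO1 replicate 3 (0.14). Of 44 microtubule regulators 3 rose and 3 fell over all genes, and 3 rose and 4 fell adjusted over the list alone (0.66). Of 32 G2/M and spindle assembly genes 1 rose and 2 fell on both counts (0.27); the anaphase activator gene Cdc20 fell by 0.18 ± 0.04 (limma adjusted p = 0.0022). The rise of Kntc1 (0.14 ± 0.04, 0.022) lost its call under edgeR, DESeq2 and median-ratio scaling and without WT replicate 1 (0.14), WT replicate 2 (0.10) or KO1 replicate 2 (0.12), and the fall of Ube2c (−0.12 ± 0.04, 0.024) without WT replicate 2 (−0.11), WT replicate 3 (−0.12) or KO1 replicate 1 (−0.11). With the KO libraries pooled as 1 group, the calls of Rrm2, Chmp2a, Ist1, Arhgef2, Tubb6, Tubb3, Cdc20, Kntc1 and Ube2c in the mean contrast were lost (adjusted p = 0.065 to 0.26). Microtubule regulators had 3 up and 4 down over all genes under quantile normalization, and 1 up and 5 down under median-ratio scaling.

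Pluripotency and fate lists were mixed. Of 29 naive and general pluripotency genes 5 rose and 5 fell over all genes, and 6 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.79), with Tdgf1 (0.24 ± 0.04) and Dppa5a (0.20 ± 0.03) up and Dppa2 (−0.26 ± 0.06) down; Tdgf1 lost its call with the KO libraries pooled (adjusted p = 0.29). The core factors Pou5f1 (2362 in WT, 2317 in KO1 and 2400.4 in KO2, adjusted p = 0.98), Nanog (−0.02 ± 0.03, 0.69) and Sox2 (0.07 ± 0.06, 0.59) had no call. Of 14 formative and primed genes 3 fell over all genes, and 2 rose and 5 fell adjusted over the list alone (0.059); over all genes 4 fell under quantile normalization and 5 under median-ratio scaling. The primitive streak and mesendoderm list (7 genes; 1 up and 2 down on both counts; 0.49), FGF/ERK immediate and feedback targets (10 genes; 2 down on both counts; 0.21) and WNT/beta-catenin targets (9 genes; 4 down on both counts; 0.11) had no call. Of 10 methylation-sensitive germline genes 2 rose and 2 fell over all genes, and 2 rose and 5 fell adjusted over the list alone (0.13). Of 24 imprinted genes 7 rose and 1 fell over all genes, and 8 rose and 1 fell adjusted over the list alone (0.49), with Dhcr7, also in the cholesterol list, and Peg10 (0.23 ± 0.04) among them.

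Of 29 p53 targets 4 rose and 1 fell over all genes, and 7 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.90); over all genes 3 rose and 2 fell under quantile normalization, and 3 rose and 3 fell under median-ratio scaling. The cell-cycle inhibitor gene Cdkn1a rose by 0.11 ± 0.04 (limma adjusted p = 0.038), a call lost under both other scalings and without WT replicate 2 (0.07), KO1 replicate 1 (0.11), KO1 replicate 3 (0.11), KO2 replicate 1 (0.11) or KO2 replicate 2 (0.10), and Mdm2 had none (−0.08 ± 0.05, 0.33). YAP/TEAD targets (14 genes; 2 up and 1 down over all genes; 5 up and 1 down adjusted over the list alone; 0.80) and integrated stress and unfolded protein response genes (26 genes; 4 up and 2 down; 7 up and 3 down adjusted over the list alone; 0.89) had no call. For the latter the counts over all genes were 3 up and 3 down under quantile normalization, and 2 up and 3 down under median-ratio scaling. Neither had primary cilium and centriole genes (42 genes, 1 up on both counts, 0.34) or ribosomal proteins (54 genes, 2 up on both counts, 0.068). For cytokinesis and midbody, tubulins and microtubule regulators the median was above 0 while camera's direction was down. For p53 targets and naive pluripotency the median and camera pointed down but the mean was above 0, and for WNT targets the median was above 0 but the mean and camera pointed down. The remaining 5 lists had fewer than 5 tested genes and no set test. The kinesin-13 family had 3 tested genes, with only Kif2a called, mesoderm 2 and trophoblast 4, with no calls, fibroblast markers 3, and the two-cell-like state 0 of its 20 genes in the table.

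The 2 knockout lines shared 69 calls in the same direction, 51 higher and 18 lower, Kif2a among the lower ones. Bhmt, Dsp, Lamb1, Dppa3 and Slc2a3 were among the shared rises, and Gpx1 among the shared falls. Both lines were compared with the same 3 WT libraries, which by itself makes their changes alike. Simulated data without effects, in which the lines shared their controls, gave 0.04 shared calls on average over 100 draws and at most 1. Independent lists as long as those of the lines would share 9.32 higher and 1.80 lower genes. The simulation leaves out the changes of each line and the independent lists leave out the shared controls, so part of the excess over either may come from the shared controls. WT is also 1 line, and the simulation holds only the spread between libraries. Any difference of the WT line from both knockout lines counts as a shared change. Beyond Kif2a, all of the excess may therefore be of this kind. A drawn partition with the KO2 libraries as the controls gave 667 shared calls. Its other groups mixed WT and KO1 libraries, so they were not the WT and KO1 lines. Across genes the correlation of the lines' log2 fold changes was 0.507 against 0.499 in that simulation, and 67.66% of genes had the same sign against 66.7%. Both lie within the range of the simulation, which reached 0.530 and 67.72%; genes are not independent replicates. The covariance was 0.00949 against 0.00372 on average and at most 0.00405 in the simulation. Called in opposite directions were 4 genes: Ddx3y, Syne2, Trh and, outside the naming rule and seen after its values, the actin-binding gene Ablim1. The fall of Ddx3y in KO2 (−0.23 ± 0.06) lost its call without KO2 replicate 1 (−0.16), and the rise of Trh in KO1 (0.25 ± 0.05) without KO1 replicate 3 (0.20). The main scaling gave 51 higher and 18 lower shared genes, quantile normalization 37 and 27, median-ratio scaling 36 and 30, edgeR 32 and 30, and DESeq2 38 and 32. Leaving out 1 library moved the shared count to 41 (without WT replicate 2), 44 (without WT replicate 3), 33 (without KO1 replicate 1) or 34 (without KO1 replicate 2).

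**Figure D3:**
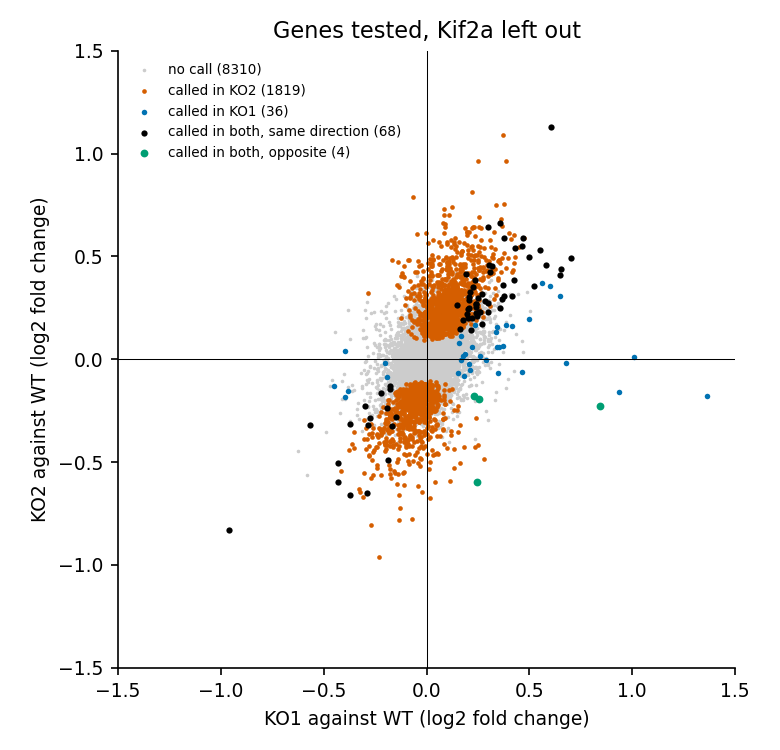
Log2 fold change in KO1 against WT (x axis) and in KO2 against WT (y axis), 1 point per tested gene, coloured by the line in which the gene was called, with Kif2a left out. Of the called genes, 1819 were called in KO2 alone and 36 in KO1 alone, 68 in both the same way and 4 in both with opposite signs.

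The direct comparison of KO2 with KO1 asks where the edited lines differ. The Y-linked genes Ddx3y and Eif2s3y were lower in KO2 than in KO1 (−1.07 ± 0.06 and −0.99 ± 0.06, limma adjusted p = 3.0e-20 for each). Ncor1 differed by −0.69 ± 0.04 (3.0e-20), and Trh, the thyrotropin-releasing hormone gene, went from 252 ± 17.3 in KO1 to 139 ± 2.92 in KO2 (8.0e-19). Axin2 differed by −0.50 ± 0.06 and the nuclear envelope gene Syne2 by −0.45 ± 0.05. Higher in KO2 were the fatty acid desaturase gene Scd1 (0.46 ± 0.04, adjusted p = 3.1e-12), the redox regulator Txnip (0.42 ± 0.05), the stress gene Ddit4 (0.42 ± 0.07), Igfbp2 (0.39 ± 0.04), A2m (0.37 ± 0.05) and Cyp51 (0.37 ± 0.06). In each of these 12 genes the 3 libraries of KO2 lay on one side of the 3 of KO1, which the naming rule required.

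Of the lists, 9 were called by camera between the knockout lines, and none held with an estimated correlation. By fry ribosomal proteins (adjusted p = 0.068) and mitochondrially encoded genes (0.20) were not called. Cholesterol synthesis was higher in KO2 with 15 of 22 genes up over all genes and 17 adjusted over the list alone (median 0.23, camera adjusted p = 3.1e-12; adjusted p = 0.12 with an estimated correlation). Hypoxia and glycolysis had 14 up and 1 down of 29 over all genes and 20 up and 1 down adjusted over the list alone (median 0.17, 1.0e-09; adjusted p = 0.37 with an estimated correlation). Ribosomal proteins had 13 of 54 up over all genes and 25 adjusted over the list alone (median 0.09, 3.5e-08; adjusted p = 0.54 with an estimated correlation). WNT/beta-catenin targets were lower, with 4 of 9 down on both counts, over all genes and adjusted over the list alone (median −0.22, 0.0023; adjusted p = 0.40 with an estimated correlation): Axin2, Ccnd1 (−0.35 ± 0.05), Notum (−0.40 ± 0.07) and Sp5 (−0.71 ± 0.14). DNA replication and S phase had 1 up and 4 down of 35 over all genes and 1 up and 5 down adjusted over the list alone (median −0.07, 0.0064; adjusted p = 0.53 with an estimated correlation). Integrated stress and unfolded protein response genes were higher, 7 up and 1 down of 26 over all genes and 8 up and 1 down adjusted over the list alone (median 0.07, 0.0078; adjusted p = 0.51 with an estimated correlation), with the amino acid transporter subunit gene Slc3a2 at 0.16 ± 0.04.

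Primitive streak and mesendoderm genes were lower in KO2 than in KO1, with 3 of 7 down over all genes and 4 adjusted over the list alone (median −0.14, camera adjusted p = 0.015; adjusted p = 0.40 with an estimated correlation), among them Nkx1-2 (−0.77 ± 0.12) and Sp5. The call was lost without KO2 replicate 3 (0.12). Sp5, T and Cdx1 are on both this list and the WNT/beta-catenin list, so the calls of these lists are not independent. Primitive endoderm genes were higher, 3 of 10 up on both counts, over all genes and adjusted over the list alone (median 0.02, 0.031; adjusted p = 0.53 with an estimated correlation), namely the collagen IV genes Col4a2 (0.57 ± 0.10) and Col4a1 and the regulator Gata4 (0.55 ± 0.13). The 9 genes of the fibroblast list in the table also summed to more in KO2, 166 ± 0.862 against 132 ± 0.632 in KO1. The primitive endoderm call was lost under quantile normalization (0.056), without KO1 replicate 1 (0.070) and without KO2 replicate 1 (0.087). Mitochondrially encoded genes were lower, with 1 of 8 down over all genes (mt-Cytb, −0.23 ± 0.05) and 2 adjusted over the list alone (median −0.20, 0.043; adjusted p = 0.54 with an estimated correlation). Their call was lost without WT replicate 1 (0.050), KO1 replicate 1 (0.097), KO1 replicate 2 (0.11), KO2 replicate 1 (0.30) or KO2 replicate 2 (0.075). Without KO2 replicate 3, whose mitochondrial share of 1.03% lay above the KO1 range of 0.906% to 1.01%, 5 of the 8 were down over all genes. In total 1016 genes differed, 482 higher and 534 lower in KO2. Quantile normalization gave 537 higher and 496 lower, edgeR 563 and 497, and edgeR with RLE factors 518 and 528. Median-ratio scaling gave 515 and 565, and DESeq2 450 and 502. Without KO1 replicate 2 the count was 521 and without KO1 replicate 3 it was 618. Of the KO2 calls against WT 729, and of the KO1 calls 36, also had a call between the lines.

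**Figure D4:**
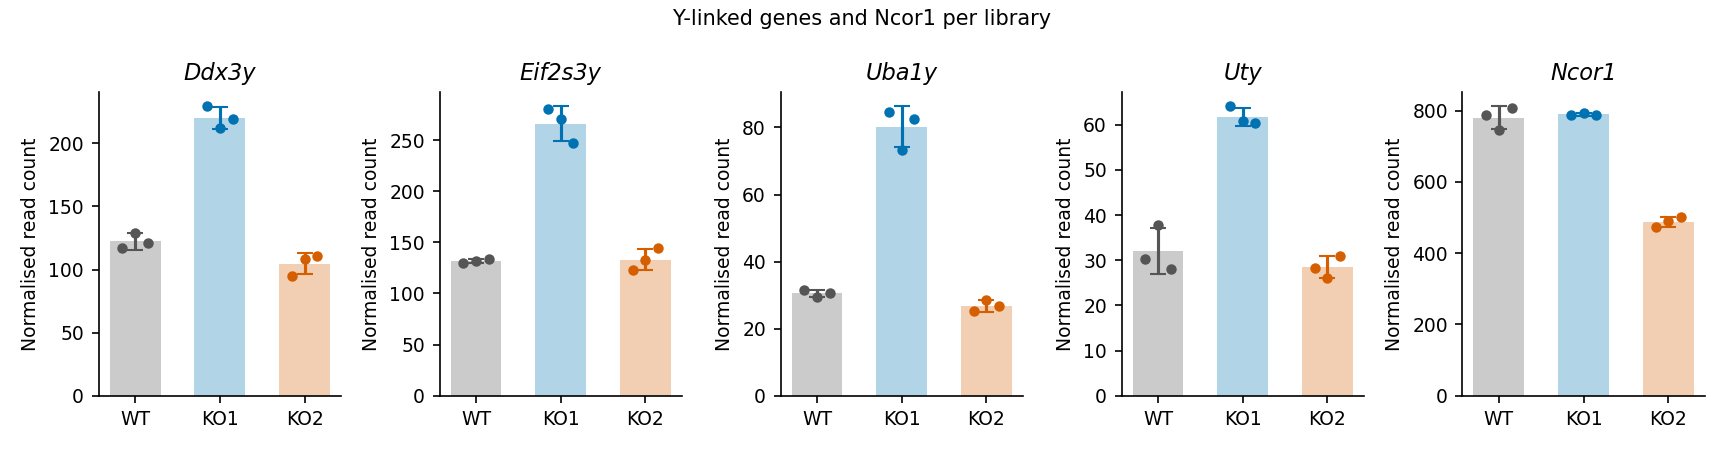
Normalised read counts (y axis) of the Y-linked genes Ddx3y, Eif2s3y, Uba1y and Uty and of Ncor1 in WT, KO1 and KO2; bars are means of 3 libraries, error bars the SD and points single libraries. Ddx3y stands at 122 in WT, 220 in KO1 and 105 in KO2, and Ncor1 at 780, 789 and 488.

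By chromosome, the 5 tested Y-linked genes had a median 0.91 above that of all genes in KO1 (camera adjusted p = 4.6e-13 over chromosomes; adjusted p = 0.020 with an estimated correlation), the set call that held in KO1 with an estimated correlation. Uba1y (30.5 ± 1.06 in WT, 80.1 ± 6.12 in KO1; 1.36 ± 0.09, limma adjusted p = 1.1e-17) and Uty (32.1 ± 5.18 and 61.8 ± 1.98; 0.94 ± 0.10, 3.1e-10) also rose, and Gm47283 did not pass the test (0.18 ± 0.13, 0.64); these 3 were named after their values were seen. Between the knockout lines the Y median, again relative to all genes, was −1.06 (camera 4.1e-10; adjusted p = 0.039 with an estimated correlation). In the mean contrast it was 0.37 (3.7e-04; adjusted p = 0.31 with an estimated correlation), and in KO2 it had no call (−0.19, 0.42). The 464 genes of chromosome 6 had a median 0.04 above that of all genes in KO1 (2.4e-04; adjusted p = 0.30 with an estimated correlation), and the 310 genes of chromosome X one 0.04 below that of all genes between KO2 and KO1 (0.026; adjusted p = 0.99 with an estimated correlation).

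At the Kif2a locus, Dimt1 (ENSMUSG00000021692, chromosome 13, 106947127 to 106960224, plus strand), a ribosomal RNA methyltransferase gene whose 3′ end overlaps that of Kif2a on the other strand, was singled out after its values were seen. It fell from 46.7 ± 4.05 in WT to 23.5 ± 2.62 in KO1 and 25.9 ± 2.94 in KO2 (−0.96 ± 0.10 and −0.83 ± 0.10, limma adjusted p = 1.6e-09 and 3.8e-08). The exons of the genes share 1229 bases, 31.9% of the Dimt1 exon length. Whether reads were counted by strand is not given in the sources used here. The next gene, Ipo11, an importin, was 225 ± 2.59 in WT and 228 ± 24.1 in KO1, and fell in KO2 to 201 ± 5.66 (−0.16 ± 0.05, limma adjusted p = 0.029), a call lost without WT replicate 2 (−0.16), WT replicate 3 (−0.16) or KO2 replicate 2 (−0.14). Zswim6, the other tested gene within 1 Mb, had no call in either line (adjusted p = 0.47 in KO2).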

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

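The tests of Dimt1, of the Y-linked genes and of the Ncor1 region and scaling were chosen only after those results had been seen, while the splits of the libraries were set before.

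Of 97 tested genes among those named here 51 differed between the knockout lines in their change against WT. The test was limma's of KO2 against KO1 with 3 libraries each. Among the named genes left out of the 97 is Kdm6a, the X-linked homologue of Uty, which also differed (limma adjusted p = 0.035). The naming rule had chosen 12 of the 51 for that difference. Others were also named for their changes, some of them in this comparison, so 51 of 97 is not a rate; of all 10238 tested genes 1016 differed. Against a shared rise or fall, Bhmt differed by −0.24, Dsp by 0.30, Dhcr7 by 0.35, Slc2a3 by 0.22, Gpx1 by −0.36, Vim by −0.30, Mllt6 by −0.16 and Trp53 by −0.13 on the log2 scale, so the rise of Bhmt was smaller in KO2 and the changes of the other 7 were larger there. Their calls in KO1 were lost on leaving out 1 library in 3 of 9 cases for Dhcr7, 4 for Vim and Trp53 and 5 for Mllt6, so a shared change is less firm for these. Higher in KO2 than in KO1 were Scd1 (0.46), Txnip (0.42), Ddit4 (0.42), Igfbp2 (0.39), A2m (0.37) and Cyp51 (0.37). Lower were Ddx3y (−1.07), Eif2s3y (−0.99), Trh (−0.85), Ncor1 (−0.69), Axin2 (−0.50) and Syne2 (−0.45). Among list members, fixed markers and genes singled out after their values were seen, those higher in KO2 were Col4a2 (0.57), Gata4 (0.55), Padi2 (0.52), Bnip3 (0.45), Col5a1 (0.42), Insig1 (0.36), Msmo1 (0.33), Col4a1 (0.30), Tdgf1 (0.30), Sox2 (0.26), Arhgef2 (0.23), Slc2a1 (0.22), Chmp2a (0.21), Slc3a2 (0.16), Itga6 (0.14) and Dppa5a (0.12). Those lower were Uba1y (−1.54), Uty (−1.09), Nkx1-2 (−0.77), Sp5 (−0.71), Hccs (−0.70), Tubb3 (−0.53), Mat2a (−0.41), Ablim1 (−0.41), Notum (−0.40), Ccnd1 (−0.35), Dppa2 (−0.32), mt-Cytb (−0.23), Ccne1 (−0.20), Ipo11 (−0.18) and Ube2c (−0.13). Since each line is 1 clone, these differences are between clones, and the genotype label does not separate them.

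Of the gene lists, 9 differed between the lines by camera with its preset correlation, and none did with an estimated one (lowest adjusted p = 0.12 with an estimated correlation). The medians were 0.23 for cholesterol synthesis, 0.17 for hypoxia and glycolysis, 0.088 for ribosomal proteins, 0.075 for integrated stress and unfolded protein response, 0.024 for primitive endoderm, −0.072 for DNA replication and S phase, −0.14 for primitive streak and mesendoderm, −0.20 for mitochondrially encoded genes and −0.22 for WNT/beta-catenin targets. Relative to all genes the median of chromosome X differed by −0.042 and that of chromosome Y by −1.06, of which the Y difference held with an estimated correlation (adjusted p = 0.039 with an estimated correlation).

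Dimt1 fell in both lines, to 23.5 ± 2.62 in KO1 and 25.9 ± 2.94 in KO2 from 46.7 ± 4.05 in WT. A loss of that size reaching Ipo11 and Zswim6, the other tested genes within 1 Mb of Kif2a, is argued against by the lowest of their changes in either line, −0.16 ± 0.05 for Ipo11 in KO2. That fall of Ipo11 was called (adjusted p = 0.029), so a smaller effect on it in KO2 stays open, as does a loss ending before it. Reads of the Kif2a 3′ end counted in Dimt1 without regard to strand remain open: Dimt1 lost 22.0, and the Kif2a value lost times the shared part of its exons gives 21.7, a ratio of 1.01 that assumes even coverage along Kif2a. That product also takes the shared bases to count in the Kif2a value. If their reads went to Dimt1 alone, the product is too low and the ratio too high. Whether overlapping reads were counted for both genes cannot be told apart from counting by strand, because 22.7% of 437 genes partly overlapping an expressed gene of the other strand had under 0.1 of the value that shared bases would bring, short of the 25% set as the bound, while 43.0% had under 0.5 of it, where double counting was to leave under 10%. Shared exons annotated in GENCODE need not be covered in these cells. Counting genes that are missing from the table as 0 would give 380 of 718 pairs under 0.1, and all 35 genes contained in exons of the other strand were missing, but a gene can be missing because of its annotation or its symbol. A real fall of Dimt1 RNA after the edit stays open and untested, so the fall may be of either kind.

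The Y-linked genes Ddx3y, Eif2s3y, Uba1y and Uty rose in KO1 to 1.80, 2.02, 2.63 and 1.93 times WT. Argued against for the genes as a set are reads shared with their X-linked homologues, whose sum moved by +43.1 beside a rise of 312 in the Y-linked genes. The sum does not settle single pairs. Ddx3x went from 948 ± 25.5 in WT to 878 ± 17.1 in KO1 (limma adjusted p = 0.16), so shared reads may add to the rise of Ddx3y from 122 to 220. Eif2s3x (312 to 322) and Uba1 (1869 to 1977) did not fall, and Kdm6a, the homologue of Uty, went from 116 to 112. Also argued against are scaling or depth, the lowest median over 5 other scalings and tests being 0.94, and fibroblast cells, whose 9 marker genes summed to only 5.40 more in KO1. The 4 changes were not equal (Cochran's Q of 23.7 against a 95% limit of 7.81), and after that was seen Uba1y was set apart: the other 3 are compatible with a common value of 0.93 (Q of 3.84 against a limit of 5.99), while Uba1y lies 4.46 standard errors above it. A higher number of Y copies per cell in KO1, or loss of Y from part of the WT and KO2 cells, may explain Ddx3y, Eif2s3y and Uty but not by itself the size of the Uba1y rise or the lack of a call for Gm47283, and no copy number was measured.

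Ncor1 (chromosome 11, 62316426 to 62458541) fell in KO2 alone, from 780 ± 31.2 to 488 ± 13.8. Loss of a larger part of the chromosome is argued against by the 15 tested genes within 1 Mb, with a median of 0.075, 4 called higher and 1, Pigl, called lower. Scaling is argued against by a change of −0.66 at its nearest to 0 over 5 other scalings and tests. A change limited to Ncor1 in the KO2 clone may explain the fall and stays a hypothesis; no biological explanation was tested, and the Ncor1 sequence was not analysed here.

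The real split of 6 libraries called 109 genes in KO1 against WT, 1892 in KO2 against WT and 1016 between the lines, against at most 0, 0 and 1 in the other splits, 1 of 10 splits reaching the real count each time; 10 splits are too few for a share under 0.05. For the mean contrast 2 of 100 drawn partitions (of 840 possible) reached 931 genes, the real one and one with the KO2 libraries as the controls, which called 1544; the next highest called 288. For genes changed in both lines the same way 2 of 100 reached 69, again the real one and that partition with 667, and the next highest gave 19. By this count a random assignment of the libraries to groups is argued against for both results. The partition with KO2 as the controls mixed WT and KO1 libraries in its other groups and still called more genes than the real one. All other drawn partitions called fewer. With 1 line per group the count cannot exclude a chance difference between lines as the source of a change against WT. The partition with KO2 as controls shows a structure of the samples, with KO2 the farthest from the other 6 libraries.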

How the results depend on the processing

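The edgeR tests and the median-ratio scaling were chosen only after the results had been seen, and the other alternatives were planned.

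The gene counts stayed within 1.5 times their main values under quantile normalization, no filter, pseudocounts of 0.1 and 10, DESeq2, edgeR with TMM or RLE factors, median-ratio scaling and the libraries of a comparison alone. Over these settings they spanned 102 to 149 genes in KO1, 1661 to 1920 in KO2, 791 to 938 in the mean contrast, 62 to 91 in both lines the same way and 930 to 1080 between the lines. Testing only genes with a mean value of at least 100 left 62, 1028, 559, 44 and 625, since fewer genes were tested. Without the trend, limma called 20, 1100, 354, 13 and 394; the cause was not tested. Requiring an absolute log2 fold change of at least 1 left 3, 3, 1, 1 and 3, by its construction, since most changes were small. Pooling the KO libraries as 1 group called 216 genes in the mean contrast, as the difference between the lines then counts as spread. The replicate number did not pair the samples, since 0 of 9 correlations between libraries of the same number exceeded 0.1 (−0.129 to 0.027); as a block it gave 89, 1719, 819, 53 and 867 genes and 6 lists.

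Leaving out 1 library gave 50 (without KO1 replicate 2) to 166 (without KO2 replicate 3) genes in KO1, 1324 (without KO2 replicate 1) to 1808 (without KO1 replicate 3) in KO2, 511 (without WT replicate 2) to 1063 (without KO2 replicate 3) in the mean contrast, 33 (without KO1 replicate 1) to 98 (without KO2 replicate 3) in both lines, and 521 (without KO1 replicate 2) to 1207 (without WT replicate 2) between the lines. The called lists of the mean contrast numbered 7, went from 5 (without WT replicate 2) to 8 (without WT replicate 1), were 5 by fry, and fell to 0 with an estimated correlation; the cause was not tested.

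Of the 287 gene results named or considered for naming, 5951 values under alternatives were computed. Of these 5456 kept their direction and their side of the threshold, or changed sign with neither value past it, 435 no longer passed, 60 newly passed, and 0 reversed. At this depth and with 3 libraries per group, the simulated recovery of 1.25-fold changes was 60% to 90%; depth was not varied on its own.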

Other observations

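Bhmt2, Dmgdh, Mat2a, Nefh, Padi2, Rhox5, Hccs and Zscan4c were chosen for this part after their values were seen, and no explanation of them was tested.

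Bhmt2 and Dmgdh rose beside Bhmt in both lines; no list of genes of betaine metabolism was tested. The neighbouring Bhmt2 went from 53.8 ± 5.38 in WT to 72.5 ± 7.92 in KO1 and 70.5 ± 7.03 in KO2 (limma adjusted p = 0.0011 and 4.8e-04), the KO1 call being lost without KO1 replicate 2 (0.34). Dmgdh, which oxidises dimethylglycine, the product of Bhmt, went from 196 ± 6.89 to 234 ± 1.76 and 230 ± 2.84 (adjusted p = 8.4e-04 and 4.6e-04). All 3 genes lie on chromosome 13, as Kif2a does, but Bhmt starts at 93616675 and Kif2a at 106958996. Relative to all genes, the 338 tested genes of chromosome 13 had a median of 0.0030 in KO1 and −0.0025 in KO2, with no call (camera adjusted p = 0.997 and 0.984). Mat2a, which makes S-adenosylmethionine, fell in KO2 from 502 ± 17.2 to 356 ± 4.37 (−0.50 ± 0.04, adjusted p = 1.4e-13) and had no call in KO1 (472 ± 7.43, adjusted p = 0.35).

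The neurofilament heavy chain gene Nefh went from 62.3 ± 2.10 in WT to 45.9 ± 1.26 in KO1 and 43.7 ± 3.38 in KO2 (limma adjusted p = 8.4e-04 and 7.3e-06), beside the falls of Nefm. Padi2, a peptidylarginine deiminase gene, rose from 27.9 ± 2.98 to 42.9 ± 3.38 and 62.0 ± 3.72 (1.1e-05 and 3.2e-14). The X-linked homeobox gene Rhox5 fell from 57.5 ± 2.22 to 38.6 ± 2.97 and 45.8 ± 1.28 (9.4e-06 and 0.0044). Hccs, the last tested gene on chromosome X (start 169250193), rose in KO1 alone, from 69.4 ± 2.0 to 112 ± 4.12 (0.68 ± 0.07, 1.4e-10), with 68.6 ± 3.48 in KO2.

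The two-cell-like gene Zscan4c lay below the filter, at 0.830 in WT, 1.94 in KO1 and 2.74 in KO2. Of the 10 genes with the largest rises by the naming rule, Itpr1, Aldh1l1, Dppa3 and Slc2a3 lie on chromosome 6. Dppa3 and Slc2a3 lie near each other, with starts at 122626410 and 122727809. The 464 tested genes of chromosome 6 had a median 0.021 above that of all genes in the mean contrast, with no call (camera adjusted p = 0.12). In KO1 against WT their median was 0.036 above, with a call (camera adjusted p = 2.4e-04, and 0.30 with an estimated correlation). In KO2 against WT it was 0.010 above, with no call (camera adjusted p = 0.98).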
